A study of Mus musculus with 4 samples.

How the data were processed

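The series holds 4 samples from mouse embryoid bodies: an anti-HA ChIP-seq library and an input library at each of 2 rescue times. The cells were embryonic stem cells with a GFP knock-in at Rx, lacking Wdr5 and carrying a doxycycline-inducible, HA-tagged human WDR5 (HA-hWDR5), per the labels. Doxycycline was given at T12h or at T48h, and the labels do not say from which event these hours are counted. The embryoid bodies were grown by the SFEBq method in 5% KSR, with 2% Matrigel from day 1. Chromatin was fixed with 2 µM disuccinimidyl glutarate for 30 min and 1% paraformaldehyde for 10 min, and 15 µg of antibody was used. The file titles place both ChIP libraries at day 6.

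Each ChIP library came as 1 peak table, called by MACS 1.4.2 on that 1 library against 1 control library, per the file headers. The calls used a p cutoff of 1e-05, an effective genome size of 2.70e+09, a band width of 300 bp and 1 tag kept per position, and the larger dataset was scaled towards the smaller. Bowtie2, SAMtools 1.5, HOMER 4.9.1, deepTools and the build mm10 are named in the submitters' processing notes. For each peak the authors deposited a tag count, which is a whole number of tags in the region, not normalised. The deposited score is the negative log10 of the MACS p-value times 10, and the fold is the ratio of tags to the local background that MACS estimated. The deposited false discovery rate is a percent from calls with ChIP and control exchanged. Peak scores and folds are therefore the authors' own, and none was recomputed. Read-level data of the ChIP and input libraries were not analysed here.

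Peaks were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A peak was shared when it overlapped a peak of the other list by at least 1 bp. The chance level came from 1000 random placements of the peaks on their own chromosomes, and from 1000 placements in which boundary peaks were moved to other gene boundaries. Peaks were assigned with the RefSeq annotation of GRCm38.p6, which is the build mm10, with 49943 genes, of which 21887 are protein-coding. The annotation used gives no strand, so the planned distance of 1 kb to a transcription start became a distance of 1 kb from the summit to either end of a gene, called a boundary peak below. A boundary peak can thus lie at the start or at the end of a gene, and it was counted for every gene within that distance.

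The lists of genes, 24 in all, and the tests were fixed before the data were examined. List membership among boundary genes was tested with a one-sided Fisher exact test against all other protein-coding genes, adjusted by Benjamini-Hochberg over 48 tests. For the list of snoRNA host genes, lncRNA genes were added to the background. Lists with at least 3 members among genes found at 1 time alone were compared between times by a two-sided Fisher exact test. Scores of shared and unshared peaks were compared within each list by a two-sided permutation test with 100000 resamples, so the smallest p is 1e-05. Intervals are exact binomial 95% intervals and cover counting error only. The 95% interval of the chromosome 8 background ratio came instead from resampling the peaks. The text names the 8 highest-scoring boundary peaks of each list, the 5 highest-scoring unshared ones, the 3 highest-scoring peaks farther than 1 kb from a boundary, up to 4 top members of each list with a boundary peak, and always Wdr5, Rax and Trp53. Other genes named were chosen after their values were seen. Some results that this rule covers are not reported here.

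With 1 library per rescue time there are no replicates, so every p-value describes peaks or genes in these libraries and not the conditions. On simulated lists, 150 of 150 planted shared peaks were recovered, the planted gene list was called in 100% of simulations, and other lists were called 0.02 times per simulation. The planted peaks began where T12h peaks begin, so their recovery was certain. Genes were drawn singly, so the rate of other calls does not cover neighbouring genes that share 1 peak. The score test called 7.5% of 40 simulations without a shift and 100% of those with a log2 shift of 1. Alternatives covered the overlap, the distance, the score limit, the list length, the genes counted and the peaks left out. Motifs, GC content and backgrounds that need a genome sequence were not analysed here.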

Results

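The comparisons address where HA-hWDR5 binds at day 6 in embryoid bodies that lack mouse Wdr5, after rescue at T12h or at T48h. Each time had 1 ChIP library and 1 input library. MACS read 90473125 ChIP tags at T12h and 124280184 at T48h, of which 55539917 and 67116740 remained after duplicate removal.

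The strongest peaks at both times lay at ribosomal protein genes, at Brd2, which encodes a bromodomain reader of acetylated histones, and in Myod1, which encodes a muscle transcription factor. At T12h the peak inside Brd2 (chromosome 17, 34118307 to 34119659) had a fold of 49.69, and its nearest boundary was that of H2-DMa at 613 bp. Other leading peaks lay at Rpl26 (33.87), the chaperonin gene Cct4 (42.67), Rpl29 (36.35) and the RNA helicase gene Ddx39b (44.64). At T48h the first peaks were a pair in Myod1 with folds of 78.16 and 50.24, against 26.21 and 27.25 at T12h, and at each time Myod1 held 3 separate peaks in its span of 2.62 kb. The Brd2 peak (30.15), Rpl23 (30.65), Rpl26 (22.33), Rpl29 (23.16), Rpl41 (24.52) and Rpl9 (26.86) came next at T48h. Of the strongest peaks farther than 1 kb from a boundary, one lay 9770 bp from Slc38a2, an amino acid transporter gene (32.21 at T12h and 19.3 at T48h). Another lay inside Eif4g3, 1874 bp from its boundary at T12h (32.47 and 20.46). A peak inside Pou3f2, a neural transcription factor gene, lay 1202 bp from its boundary, with a fold of 21.05 at T12h and 7.66 at T48h. The Pou3f2 peak held 451 tags over 1501 bp at T12h and 20 tags over 196 bp at T48h, so these counts do not cover the same region. Plasmid or cDNA in the libraries was not excluded for this peak or for those in Myod1. No peak lay in or within 1 kb of Wdr5, Rax or Trp53.

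The T12h list held 1197 peaks and the T48h list 660. The median width was 359 bp at T12h and 297 bp at T48h, and the lists covered 623 kb and 320 kb. The median fold was 7.31 at T12h and 7.66 at T48h. A fold of at least 20 was reached by 85 peaks at T12h and 38 at T48h. Peaks held 0.182% of the filtered tags at T12h and 0.0854% at T48h. The deposited false discovery rate had a median of 3% at T12h and 9.63% at T48h, and was 50% for the top T12h peak.

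**Figure D1:**
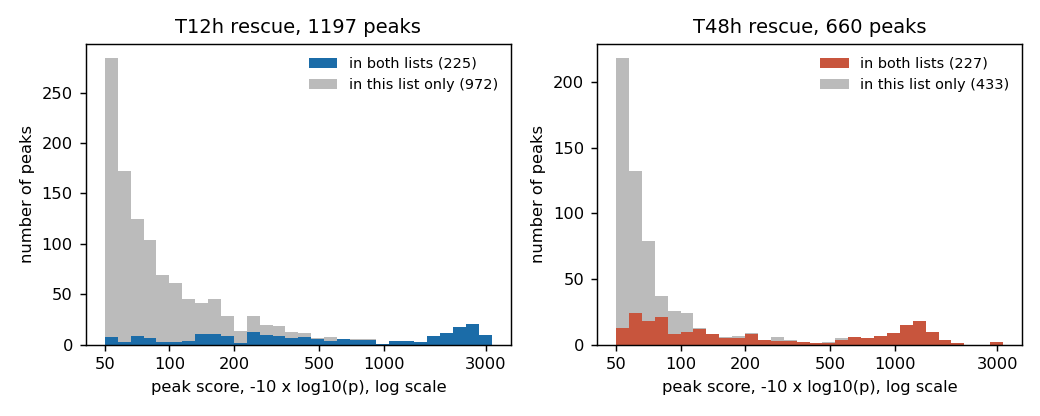
Number of peaks by the authors' score (log axis) in the T12h list and the T48h list, with peaks found in both lists in colour and peaks of 1 list alone in grey. The 82 T12h peaks and 50 T48h peaks with a score of at least 1000 were all shared.

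The second comparison asked whether both rescue times gave the same sites, and the strong sites, those of Brd2, Cct4 and the ribosomal protein genes among them, were found at both. Of the T12h peaks, 225 (18.8%, interval 16.6 to 21.1) overlapped a T48h peak, and of the T48h peaks, 227 (34.4%, 30.8 to 38.2) overlapped a T12h peak. The shared share was 31.7% for T12h when its list was limited to the length of the T48h list. It was 30.2% and 55.0% when the upper part of each list by score was compared with the upper part of the other. Random placements shared 0.357 T12h peaks on average, and placements at other gene boundaries 2.74. Of the 100 highest-scoring peaks, 98 at T12h and 94 at T48h were shared. Of peaks in the lower part of the score order, 21 of 599 at T12h and 32 of 330 at T48h were shared with a peak anywhere in the other list. The strongest boundary peaks of T12h without a T48h counterpart lay at Dpy19l2 (fold 19.26), Mga (11.55), Fam229b (12.45), Prxl2a (14.72) and E2f6 (12.97). Those of T48h without a T12h counterpart lay at Mycn (9.15), the eye field genes Lhx2 (12.15) and Six6 (17.03), the pluripotency gene Esrrb (11.47) and the kinase gene Clk4 (7.36).

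Shared peaks had higher scores than unshared ones in each list. The median score at T12h was 415.59 for shared and 69.4 for unshared peaks, a log2 difference of 2.58 (two-sided permutation p = 1e-05, the smallest possible). At T48h the medians were 149.12 and 57.86, a log2 difference of 1.37 (permutation p = 1e-05, the smallest possible). With the fold in place of the score the log2 differences were smaller, 1.03 at T12h and 0.26 at T48h (permutation p = 1e-05 for each). Across 224 shared pairs the log2 scores of both times were related, with Pearson r = 0.865 and Spearman rho = 0.801 (permutation p = 1e-05 for each). Peaks are not independent replicates. The fold was higher at T12h in 192 of the 224 pairs, with a median of 14.3 against 8.77, while the 3 peaks inside Myod1 had higher folds at T48h.

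**Figure D2:**
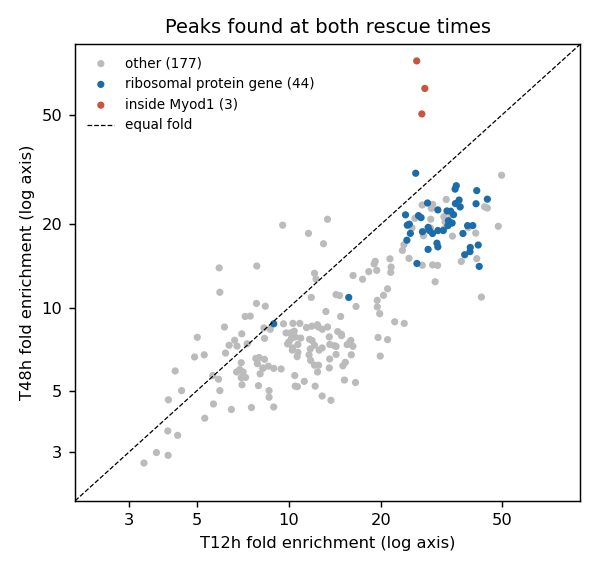
Fold enrichment at T12h (horizontal, log axis) and T48h (vertical, log axis) for 224 shared peak pairs. Blue marks 44 boundary peaks of ribosomal protein genes, red marks 3 peaks inside Myod1, and the dashed line marks equal fold. Most ribosomal protein genes lie under the line, and the Myod1 peaks lie above it.

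The third comparison asked where the peaks lay relative to genes. Rpl26, Cct4 and Ddx39b had summits 221, 116 and 245 bp from a gene boundary at T12h. Of the T12h peaks, 697 (58.2%, 55.4 to 61.0) were boundary peaks, and of the T48h peaks, 256 (38.8%, 35.1 to 42.6), against 6.40% and 6.18% in random placements. The odds ratio between the lists was 2.20 (two-sided Fisher exact test, adjusted p = 9.8e-16 over 4 tests), and 3.96 when the T12h list was limited to as many top-scoring peaks as the T48h list. Shared peaks were at boundaries in 81.3% at T12h and 81.9% at T48h. Unshared peaks were at boundaries in 52.9% at T12h and 16.2% at T48h, an odds ratio of 5.82 (Fisher exact test, adjusted p = 1.4e-40). Protein-coding genes with a boundary peak numbered 642 at T12h and 233 at T48h, with 188 in both, where independent lists would share 6.83.

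Cytosolic ribosomal protein genes, which encode the translation machinery, were the most frequent group of boundary genes. Of 86 members, 44 (51.2%, 40.1 to 62.1) had a boundary peak at each time, and they were the same 44 genes. Other protein-coding genes had one in 2.74% at T12h and 0.867% at T48h (one-sided Fisher exact test, adjusted p = 4.2e-43 and 4.7e-63). The median fold at these genes was 32.5 at T12h and 19.8 at T48h. Of the 100 highest-scoring peaks of either list, 43 were boundary peaks of ribosomal protein genes. Rpl17, Rpl18 and Rps2 had shared peaks inside the gene, farther than 1 kb from its boundaries, and the counts of boundary peaks leave these out. Large-subunit genes had a boundary peak in 31 of 52 and small-subunit genes in 13 of 32, which did not differ by the two-sided Fisher exact test (p = 0.117).

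**Figure D3:**
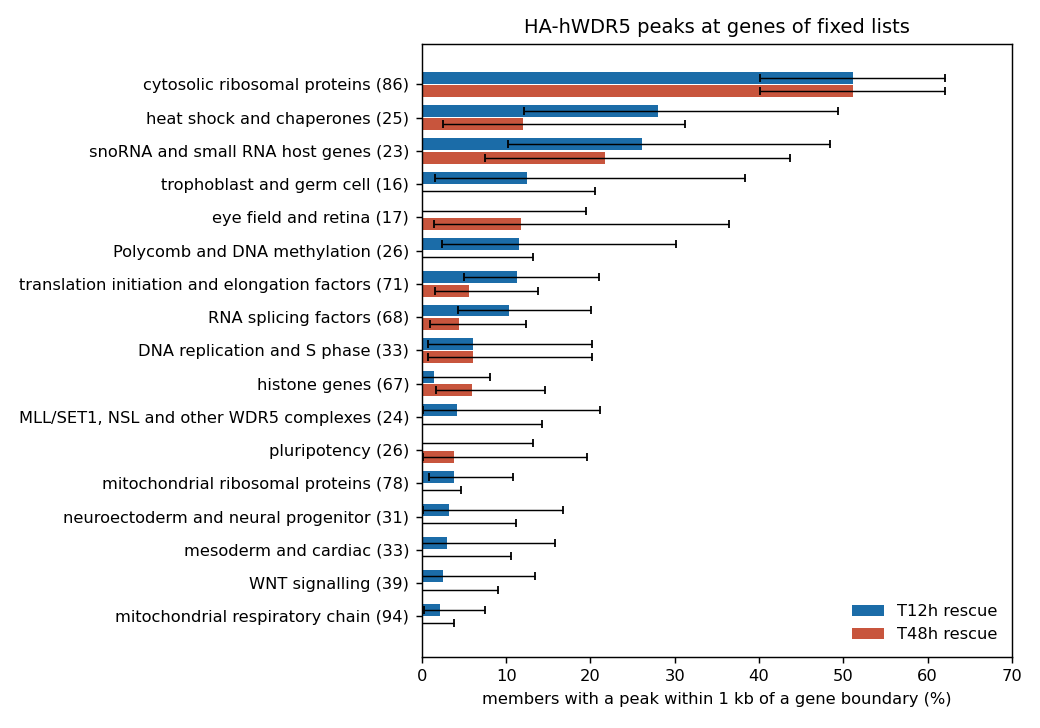
Percent of members of each gene list with a boundary peak at T12h (blue) and T48h (red), with exact binomial 95% intervals and the number of members in brackets. Cytosolic ribosomal protein genes reach 51.2% at both times.

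Of 23 snoRNA host genes, whose introns carry small nucleolar RNAs, 6 had a boundary peak at T12h (Fisher exact test, adjusted p = 7.7e-05) and 5 at T48h (1.3e-05). Snhg17 (fold 32.18 at T12h and 21.32 at T48h), Rack1 (30.69 and 14.22) and Snhg15 (29.56 and 14.28) led them, and Snhg9 followed. The peak counted for Snhg9 is the one inside Rps2. Of 25 heat shock and chaperone genes, 7 had a peak at T12h (Fisher exact test, adjusted p = 6.6e-05) and 3 at T48h (0.0158). These were led by Cct4 (42.67 and 10.92), Cct7 (27.31 and 23.52) and Hspa1b (13.74 and 4.62), and Hspa1a had a peak at T12h (10.37). Of 71 translation factor genes, 8 had a peak at T12h (Fisher exact test, adjusted p = 0.00878) and 4 at T48h (0.0334), namely Eif3d (29.26 and 22.88), Eef1g (29.58 and 23.64), Eef2 (27.58 and 18.2) and Eif4g1 (21.05 and 11.7) at both. Of 68 splicing factor genes, 7 had a peak at T12h (Fisher exact test, adjusted p = 0.0224) and 3 at T48h (0.144). Snrpb (33.87 and 21.78), Sf3b3 (23.54 and 16.11) and Prpf3 (19.4 and 13.65) had one at both times, and Hnrnpk at T12h (8.78). The splicing call at T12h was lost at 5 kb (adjusted p = 0.105 by the Fisher exact test) and under 3 other settings. The chaperone call at T48h was lost in the upper part of the list by score (Fisher exact test, adjusted p = 0.0763) and when each peak counted for its nearest gene alone (0.108).

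Among the developmental lists no call was made at 1 kb. Lhx2 and Six6 were the 2 of 17 eye field genes with a peak at T48h, or 11.8% against 1.06% of other genes (Fisher exact test, adjusted p = 0.0603), and none of that list had one at T12h. The eye field list was called at T48h at 5 kb (Fisher exact test, adjusted p = 0.0205) and in the upper part of the list by score (0.0485). At 5 kb, 3 eye field genes were found at T48h alone and 1 at T12h alone. Lhx2 held 5 T48h peaks, and plasmid or cDNA was not excluded as their source. Of the pluripotency genes, Esrrb had a peak at T48h (Fisher exact test, adjusted p = 0.712). At T12h the Polycomb genes Rybp (fold 9.82), Ezh2 (9.92) and Suz12 (6.34) had peaks, 3 of 26 or 11.5% against 2.92% of other genes (Fisher exact test, adjusted p = 0.146). The Ezh2 peak lies in a 1 Mb window of chromosome 6 that held 23 T12h peaks. Ascl2 (8.93) and Dazl (6.39) were 2 of 16 trophoblast and germ cell genes at T12h, or 12.5% against 2.93% of other genes (Fisher exact test, adjusted p = 0.252). Single members had a peak at T12h in the lists of neural progenitor genes (Nes, 8.37), mesoderm genes (Mesp2, 7.14), WNT genes (Sfrp2, 7.76) and WDR5 complex genes (Phf20, 7.94), each with an adjusted p of 1. Mitochondrial ribosomal genes had 3 members with a T12h peak (Mrps15, Mrpl48 and Mrpl21) and respiratory chain genes 2 (Ndufa13 and Atp5g2), with an adjusted p of 1 in each list. No member had a boundary peak at either time among 29 p53 targets, 39 Hox genes, 35 aminoacyl-tRNA synthetases, 39 proteasome subunits, 16 endoderm genes, 24 mitosis genes and 1459 olfactory and vomeronasal receptors.

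Between the times, histone genes differed, with 4 of the 45 genes found at T48h alone and 1 of the 454 found at T12h alone (two-sided Fisher exact test, adjusted p = 0.00164 over 6 lists). The 4 were H2ac7 with H2bc7 and H2ac8 with H2bc8, and each pair of neighbours shared 1 peak, with folds of 4.74 and 6.75. The list was also called at T48h on its own (4 of 67, one-sided Fisher exact test, adjusted p = 0.0303), and at T12h 1 of 67 had a peak (H2bc14, adjusted p = 1). The T12h peak of H2bc14 also lay at H2ac14, which the annotation gives as a pseudogene and which is outside the protein-coding genes tested. Counting each peak for its nearest gene alone ended both calls (Fisher exact tests, adjusted p = 0.444 at T48h and 0.0779 between times). Taking the upper part of each list by score also ended both, with 0 histone genes left at T48h. The other 5 lists tested between times had an adjusted p of 1.

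In both lists some peaks lay together inside single genes. Lhx2 held 5 T48h peaks and none at T12h, and Nr3c1, the glucocorticoid receptor gene, held 4 and none. Esrrb held 5 T48h peaks, 2 of them shared with T12h. Myod1 held 3 at each time, and Ezh2 and Gm26650 held 3 at T12h. Ezh2 lies in a 1 Mb window of chromosome 6 that held 23 T12h peaks, with a median fold of 3.75. Rnf220 held 3 at T48h, and these overlapped 1 T12h peak of 1195 bp with a fold of 36.69. Nr3c1, Rnf220 and Gm26650 were chosen after their values were seen.

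**Figure D4:**
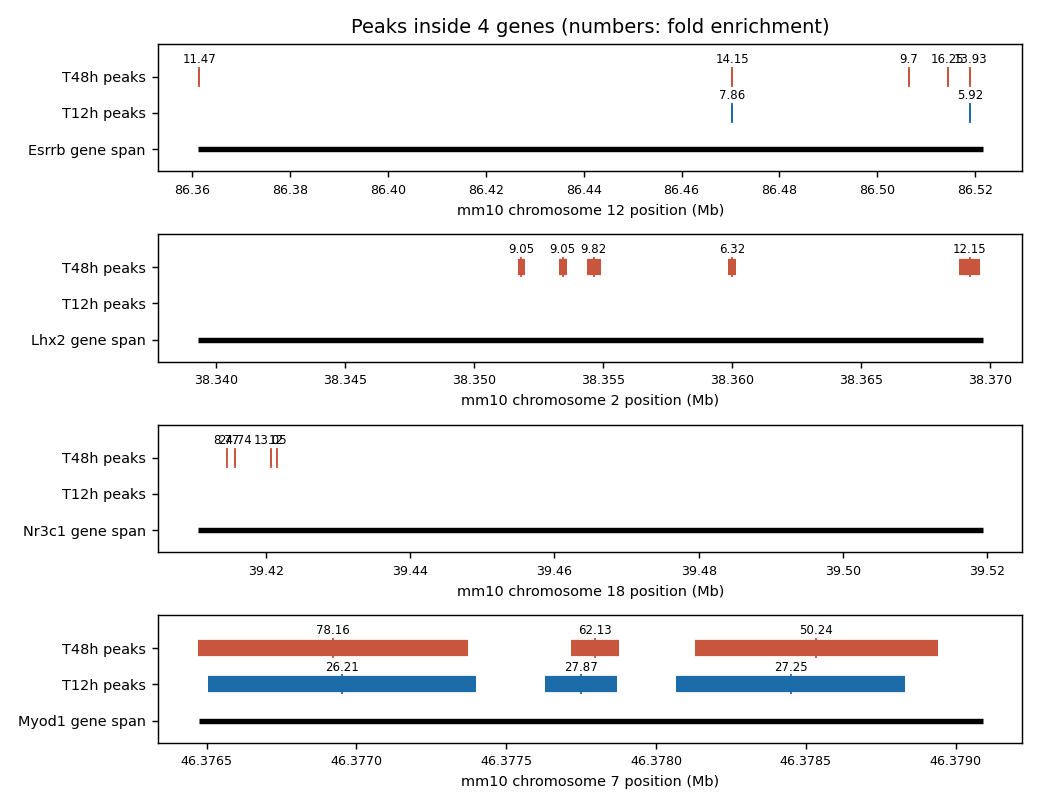
Peaks of the T48h list (red) and the T12h list (blue) along Esrrb, Lhx2, Nr3c1 and Myod1 on mm10, with the gene span in black, position in Mb on the horizontal axis and the fold above each peak. Lhx2 and Nr3c1 held peaks at T48h alone.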

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

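Leaving out chromosome 8 or dense windows, and counting only the nearest gene, were chosen after the data were seen. Cytosolic ribosomal protein genes were called in every setting run. Taking the upper 50% of each list by score left 600 and 331 peaks, raised the shared share to 30.2% at T12h and 55.0% at T48h and the boundary share to 73.0% and 55.3%, left no histone gene with a T48h peak (0 members) and called 0 lists between times. Requiring overlap of 50% of both peaks gave shared shares of 16.5% and 29.8%. Equal list lengths gave 31.7% shared and 71.5% at boundaries for T12h. The boundary share at 500 bp was 46.4% and 32.4%, at 5 kb 74.7% and 53.6%, and with protein-coding genes alone 47.3% and 29.8%, for T12h and T48h. At 5 kb 2 lists were called between times, histone genes and eye field genes (Fisher exact test, adjusted p = 0.0233 for the latter). Counting the single nearest gene called 3 lists at T48h, where the histone and chaperone lists fell to 2 members each, and 0 between times, since each peak then counts for 1 gene. For the other changes the cause was not tested. Of all values recomputed, 103 kept their size or side of the threshold, 20 moved, 9 lost their call and 1 reversed. No paired analysis was possible because each group held 1 library. Alternatives that need a genome sequence (CpG-promoter background, GC-matched random lists, motif settings and GC windows) were not run.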

Other observations

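All tests in this part were chosen after the results were seen. Ribosomal RNA genes had boundary peaks in 16 of 63 at T12h and 8 of 63 at T48h, with median folds of 3.71 and 3.65. Of these 63 genes, 48 lie in 1 window of 1 Mb on chromosome 8 (123 to 124 Mb). That window held 17 T12h peaks and 8 T48h peaks, with a median fold of 4.03 at T12h. The counts therefore need not hold for ribosomal RNA genes elsewhere. snoRNA genes had one in 20 of 1340 and 16 of 1340, with median folds of 26.0 and 19.9. Windows of 1 Mb with 6 or more peaks held 135 T12h peaks and 40 T48h peaks, and the median fold there was 4.45 against 7.59 elsewhere at T12h. Chromosome 12 held 36 T48h peaks against 19.2 expected from its share of protein-coding genes, a ratio of 1.87 (1.32 to 2.56). Its implied background was 0.905 times that of other autosomes. The interval treats peaks as independent, although 5 of these lay in Esrrb and others lay together in Mycn and Six6. Chromosome Y held 14 T48h peaks outside dense windows against 7.25 expected, a ratio of 1.93 (1.06 to 3.21). At T12h it held 2 against 12.4 expected, a ratio of 0.161 (0.0195 to 0.580). These expected numbers follow protein-coding genes, although only 38.8% of T48h peaks were boundary peaks. The share of genes may thus be a poor chance level, and no excess is claimed for chromosome 12 or Y.

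The T12h-only peaks at E2f6 and Mga, which encode subunits of the repressive complex PRC1.6, led to a list of germline genes known as targets of that complex, written after the T12h peaks had been looked through. The list of zinc finger protein genes was written after peaks at Zfp105 and Zfp280d had been seen. Of the 22 germline genes, 5 had a T12h boundary peak (Dazl, Smc1b, Tdrkh, Tex14 and Zcwpw1), and 0 had one at T48h. The T12h share was 22.7% against 2.91% of other genes (one-sided Fisher exact test, p = 0.00037, adjusted over 4 tests 0.00074). Of 397 protein-coding zinc finger genes, 28 had a T12h peak (Zfp783, a lncRNA in the annotation, is not counted), or 7.05% against 2.86% (Fisher exact test, p = 1.9e-05, adjusted 7.7e-05), and 8 had one at T48h (Fisher exact test, p = 0.063, adjusted 0.084). Both lists were prompted by the same peaks they were tested on, so these p-values are no independent evidence.

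T12h peaks were dense on chromosome 8, with 130 of them. Clusters of repeated genes did not account for all of it. Outside dense windows there were still 1.80 times as many peaks as the chromosome's share of protein-coding genes predicts (1.46 to 2.19). Extra copies of chromosome 8 may contribute: the background implied by tags, fold and width was 1.43 times that of other autosomes (lower end of the 95% interval 1.36, permutation p = 1e-05). The same background was raised at T48h (1.31), where the density was 1.05, so gain of the chromosome and a true difference in binding cannot be told apart. Input reads, which would show a gain directly, were not analysed here.

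T48h peaks stacked in Lhx2, Nr3c1 and Esrrb, and the same test was not run at T12h, where Gm26650 held 3 unshared peaks. Of 1000 random placements, 1 gave as many as 3 genes with 3 or more unshared T48h peaks, so placement at random positions rarely gave this count. The count tested was also the one that had prompted the test. DNA with sharp ends, such as plasmid or cDNA, may add such peaks, and stacked peaks were 0.759 times as wide as shared boundary peaks of the same score range (310.5 against 409 bp, permutation p = 0.0503). The explanation stays open, for Myod1 too, whose shared peaks were outside the test, and exon positions were not used here. The width test cannot settle it, since the widths that such DNA would give were not known. Mycn and Six6, with more than 1 T48h peak each, and Pou3f2 were also outside the test. Pgk1 had T48h peaks near each of its ends, with folds of 20.89 and 8.51, and the first had 13.39 at T12h. Binding of HA-hWDR5 to these genes after rescue at T48h stays untested, with 1 library per time.

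Many T12h boundary peaks had no T48h counterpart. If lower enrichment at T48h had put them under the threshold of 50, the score ratios at 95 boundary peaks of score 500 or more, outside Myod1 and with the 3 unshared ones at their upper bound, would give 72.1 shared among the 78 of score 200 to 500, and 43 were shared. That number assumes a constant ratio, but the ratio was smaller at lower scores (rho = 0.274, permutation p = 0.00736), so lower enrichment may account for the difference and cannot be told apart from a difference between rescue times with 1 library each. With the 92 shared peaks alone, as first run, 74.4 were expected and the relation was weaker (rho = 0.205, permutation p = 0.0505), which would have counted against lower enrichment as the whole cause. Another bound tried after that, the lowest ratio of 0.0859 among those 92, would predict 0 shared peaks and exclude nothing.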
